A study of Mus musculus with 3 samples.

How the data were processed

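ChIP-seq libraries were made from suprabasal keratinocytes of wild-type BALB/c mice with antibodies against DLX3 and H3K4me3 and with nonspecific immunoglobulin (IgG), 1 library each. Per the labels' protocols, cells were cross-linked with formaldehyde, chromatin was sonicated and immunoprecipitated, and libraries were amplified by PCR and sequenced on Illumina HiSeq instruments. The series text describes cells of newborn epidermis separated on a density gradient, while the sample labels give the animals as adult; which holds was not settled here.

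Each of the DLX3 and H3K4me3 libraries came with 1 deposited peak list on mm10. The IgG library came without a list of its own and was not analysed here. The names of both lists mention IgG, but whether it served as the control for the calls is not given in the sources used here. If it did, reads shared with that control would act on both lists alike, which was not tested. Per the submitters' processing notes, the tools were Bowtie 1.1.2, MACS 1.4.2 and HOMER with genome build mm10; their settings and roles are not given in the sources used here. The deposited lists hold chromosome, start, end, name and a score for each peak, and the authors made 1 list per library, so nothing was pooled. The deposited scores run from 50.01 to 3100 for DLX3 and from 50 to 3233.06 for H3K4me3. This range has the form of the MACS 1.4 peak score, 10 times the negative log10 of the p-value, with every peak at a p of 1e-05 or below, and 766 H3K4me3 peaks stand at exactly 3100, a ceiling. The score depends on depth and peak width, so scores were compared within a list only. The exception is chromosome X, where a ratio of H3K4me3 scores was applied to the DLX3 score threshold. Depth per library is unknown, since the lists hold no read counts, and intervals given for shares of peaks cover counting error only.

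Peak positions are given counting from 1. Genes came from a RefSeq gene table of GRCm38.p6, the same assembly as mm10, with 49980 genes, of which 21900 are protein-coding. The table gives spans without strand or exons, so the planned windows round transcription start sites were replaced by windows round both ends of each gene span, and exons, introns and untranslated regions were not separated. No genome sequence was used here, so 24 planned sequence motifs, the homeodomain core among them, were not searched, and assembly gaps were not excluded from random placement; placements were drawn between the outermost gene or peak of each chromosome.

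Overlap of DLX3 with H3K4me3 required at least 1 bp. It was compared with 1000 random placements that kept chromosome and peak width (two-sided permutation p, at least 0.002). The same placements served for the share of peaks centred within 1 kb of a protein-coding gene end. Shares carry 95% Wilson intervals. Deciles of the DLX3 score were compared by Fisher's exact test with an odds ratio. Because genes and peaks of 1 library are not replicates, these tests describe the lists.

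Before the data were examined, 24 gene lists were fixed: epidermal differentiation complex, cornified envelope and lipid barrier, desmosome and tight junction, keratinocyte transcription factors, Notch, Wnt and BMP signalling, IL-6, STAT3 and cytokines, p53 and arrest, cell cycle progression, hair keratins, tooth and bone, markers of basal and suprabasal keratinocytes, hair follicle, fibroblast, melanocyte, immune, endothelial and neuronal cells, ribosomal proteins, olfactory receptors, keratin-associated proteins, Hox genes, histones and defensins. The symbols Sprr2g, Bleh1, Il36rn, Tp53inp1, Krt74, Krt85 and Trdc matched no gene. The histone list was taken by symbol pattern and includes H13, which is not a histone gene. For DLX3, a gene counted when any base of a peak lay within 5 kb of either end of its span, and each count was set against 10000 random protein-coding lists with the same number of H3K4me3-marked genes (H3K4me3 within 1 kb of an end). For H3K4me3, random lists were unmatched. P-values were two-sided, adjusted by the Benjamini-Hochberg method over the 24 lists, with a threshold of 0.05. Genes that share a peak were counted separately.

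Genes named in the text follow a rule fixed in advance: in each list the 4 members with the highest-scoring DLX3 peak within 5 kb (the ribosomal protein list is given by its count alone), the protein-coding genes nearest to the 10 highest-scoring DLX3 peaks, and always Dlx3, Trp63, Socs3, Stat3, Krt1, Krt10, Krt5, Krt14, Lor, Flg and Ivl. Ties went to the wider peak, then to the lower position. In the closing part, lists of 38 immediate-early and 20 heat-shock genes were added after the data were seen, as were the genes named with the broadest H3K4me3 peaks and the highest span coverage.

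Alternatives covered other definitions of overlap, peaks at or above the median score and in the top 20% of each list (for DLX3 gene lists this changes the DLX3 peaks and the H3K4me3 marks used for matching together), rotation of all peaks along each chromosome, windows of 500 bp, 1 kb, 2.5 kb and 20 kb, all annotated genes and no matching. Others were added after the data were seen: any peak base in the promoter window, the gene span with 5 kb on either side, matching on gene density or length, leaving out the 50 highest-scoring peaks, peaks near immediate-early and heat-shock genes or those genes as list members, and autosomes only.

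The procedures were tested on simulated data. Of 2000 sets of 18087 unrelated peaks, 4.75% were called as overlapping H3K4me3, and with 5% of peaks planted on H3K4me3, 100% were called. The unrelated sets were drawn by the same random placement as the comparison. These rates therefore check the calculation and not whether random placement suits ChIP peaks. Of 400 random lists of 30 genes among 21900, 3% were called at an unadjusted permutation p of at most 0.05. Of lists with a 1.5-fold higher share of genes with peaks, 45.5% were called, so lists of that size with a modest excess are often missed. Genes were simulated independently and without adjustment over lists. The rates therefore do not cover adjusted calls or lists whose genes lie in clusters and share peaks. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.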

Results

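Chromatin was profiled in suprabasal keratinocytes, the differentiating cells above the basal layer of the epidermis, from wild-type BALB/c mice. The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which an antibody recovers the DNA fragments bound by its target. An antibody against DLX3, a homeodomain transcription factor of differentiating epidermis, hair and teeth, gave 1 library. An antibody against H3K4me3, trimethylated lysine 4 of histone H3, a mark of active promoters, gave another, and nonspecific immunoglobulin (IgG) gave the third. Each antibody has 1 library, so there is no replicate spread, and every test below describes these 2 peak lists and not the variation between animals. The DLX3 list held 18087 peaks covering 12.03 Mb, with a median width of 627 bp (interquartile range 505 to 774) and a median score of 83.35. The H3K4me3 list held 16735 peaks covering 38.8 Mb, with a median width of 2080 bp (1508 to 2801) and a median score of 823.67. Read depths were not given in the files used here.

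The first comparison asked how far the sites of DLX3 coincide with promoters that carry H3K4me3. DLX3 and H3K4me3 peaks coincided at, among others, Perp, a desmosomal membrane protein gene and p53 target, Ctnnb1, which encodes β-catenin, Stat3, a transcription factor gene of cytokine signalling, and Cdk4, a cell cycle kinase gene. The DLX3 peak at Perp (chromosome 10, 18844592 to 18845430, mm10; score 410.54) was centred 60 bp from an end of the gene, inside an H3K4me3 peak of 10484 bp. The peak at Stat3 (chromosome 11, 100939297 to 100940123; score 455.11) was centred 115 bp from a gene end, and the peak at Cdk4 (chromosome 10, 127063083 to 127064043; score 475.04) was centred 28 bp from one. In all, 7615 of the 18087 DLX3 peaks (42.1%, 95% Wilson interval 41.4 to 42.8) shared at least 1 bp with an H3K4me3 peak. Of the 16735 H3K4me3 peaks, 6816 (40.7%, 40.0 to 41.5) met a DLX3 peak. Random placement of the DLX3 peaks on their chromosomes gave a mean overlap of 2.08% (1.87 to 2.27 over 1000 placements), so the observed share was 20.3-fold higher (two-sided permutation p = 0.002, the smallest these placements can give). With both lists restricted to their top 20% by score, 25.3% of DLX3 peaks met an H3K4me3 peak, 38.2-fold over placement. Active promoters may draw peaks in any ChIP, and placement over whole chromosomes does not allow for that. These folds, and the comparisons by score and gene end below, therefore do not separate DLX3 binding from such signal. The IgG library was not analysed.

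Higher-scoring DLX3 peaks lay on H3K4me3 more often. In the lowest decile of DLX3 scores (median 52.11), 29.4% of peaks overlapped H3K4me3 (27.4 to 31.6), and in the highest decile (median 242.32) 59.1% did (56.8 to 61.3). The odds ratio between these deciles was 3.46 (95% interval 3.02 to 3.98; two-sided Fisher's exact test, p = 4.1e-73), and 1.86 (1.76 to 1.98) between the peaks above and below the median score. Wider peaks meet other intervals more easily, and the median width rose from 491 bp in the lowest decile to 872 bp in the highest. Counting only DLX3 peaks whose centre lay inside an H3K4me3 peak gave an odds ratio of 3.47. The rise was not steady at the bottom, since the lowest 3 deciles gave 29.4%, 35.3% and 29.9%.

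**Figure D1:**
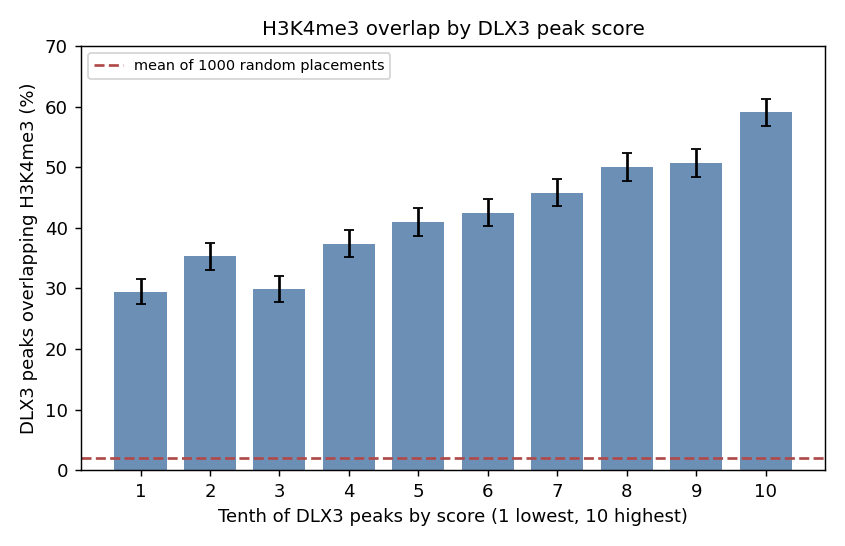
Percent of DLX3 peaks (vertical axis) that overlapped an H3K4me3 peak in each decile of the DLX3 score (horizontal axis, 1 lowest and 10 highest). Bars are shares of single lists with 95% Wilson intervals, the dashed line is the mean of 1000 random placements at 2.08%, and the share goes from 29.4% in the lowest decile to 59.1% in the highest.

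The next comparison placed the peaks of each antibody relative to genes. H3K4me3 was concentrated at the ends of protein-coding genes, and DLX3 was found both there and at many sites inside and between genes. At Jup, the gene of plakoglobin, the top DLX3 peak (chromosome 11, 100396842 to 100398879; score 256.26) was centred 21 bp from a gene end, whereas at Notch1, a receptor gene of keratinocyte differentiation, the top peak (chromosome 2, 26507346 to 26507890; score 286.27) was centred 3795 bp outside the gene, without H3K4me3. Of the DLX3 peaks, 5209 (28.8%, 28.1 to 29.5) were centred within 1 kb of a gene end, against 3.18% under random placement (9.06-fold, two-sided permutation p = 0.002). Of the H3K4me3 peaks, 9952 (59.5%, 58.7 to 60.2) were, against 3.21% (18.5-fold, permutation p = 0.002). As for the overlap, random placement does not allow for promoters that draw peaks in any ChIP. A further 37.0% of DLX3 peaks were centred inside a gene span more than 1 kb from its ends, 14.5% outside spans at 1 to 20 kb from a gene end, and 19.7% outside spans and beyond 20 kb. The annotation used gives gene spans without strand or exons, so an end can be the start or the finish of a gene, and introns, exons and untranslated regions were not told apart.

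DLX3 peaks with and without H3K4me3 had different positions. The 7615 peaks with H3K4me3 lay at a median of 235 bp from the nearest gene end, and 64.8% (63.8 to 65.9) were within 1 kb of one. The 10472 without it lay at a median of 26274 bp, and 2.597% (2.31 to 2.92) were within 1 kb of a gene end, while 46.6% were inside gene spans and 31.2% outside spans and beyond 20 kb. Their median score was 76.83, against 93.79 with H3K4me3. Among 9004 protein-coding genes longer than 10 kb with H3K4me3 at exactly 1 of their ends, DLX3 lay within 1 kb of the marked end in 3971 (44.1%, 43.1 to 45.1) and of the unmarked end in 140 (1.55%, 1.32 to 1.83). DLX3 was at the marked end alone in 3897 of them and at the unmarked end alone in 66. Of all 21900 protein-coding genes, 12988 (59.3%) had H3K4me3 within 1 kb of an end. A DLX3 peak lay within 5 kb of an end in 7121 of these 12988 (54.8%) and in 723 of the 8912 others (8.11%).

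Dlx3 itself and the regulator genes named in advance carried DLX3 peaks, and of the differentiation genes Krt1, Ivl and Flg did not. A DLX3 peak of score 185.43 (chromosome 11, 95117709 to 95118926) was centred 1799 bp from an end of Dlx3, outside the gene, and overlapped an H3K4me3 peak of 8290 bp. Trp63, which encodes the epithelial master regulator p63, had no peak within 5 kb of its ends, but 9 DLX3 peaks lay over its span with 5 kb on either side (gene span chromosome 16, 25683763 to 25892088), the highest scoring 131.91, and 1 H3K4me3 peak of 6027 bp lay inside the gene. Socs3, a feedback inhibitor gene of cytokine signalling, had a DLX3 peak of score 102.51 (chromosome 11, 117963119 to 117963766), 2636 bp from an end. Among the keratin genes, Krt5 (105.22; chromosome 15, 101713595 to 101714224) and Krt14 (100.53; chromosome 11, 100205471 to 100206224), which mark basal cells, had a DLX3 peak, as did Krt10 (69.06; chromosome 11, 99386943 to 99387784), a keratin gene of suprabasal cells. Krt1, its partner, had H3K4me3 (score 377.61) and no DLX3 peak. Of the cornified envelope genes, Lor (loricrin) had a DLX3 peak of score 76.44 (chromosome 3, 92080930 to 92081795) that overlapped H3K4me3, whose score was 2180.19, Ivl (involucrin) had H3K4me3 alone at a score of 76.82, and Flg (filaggrin) had neither.

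**Figure D2:**
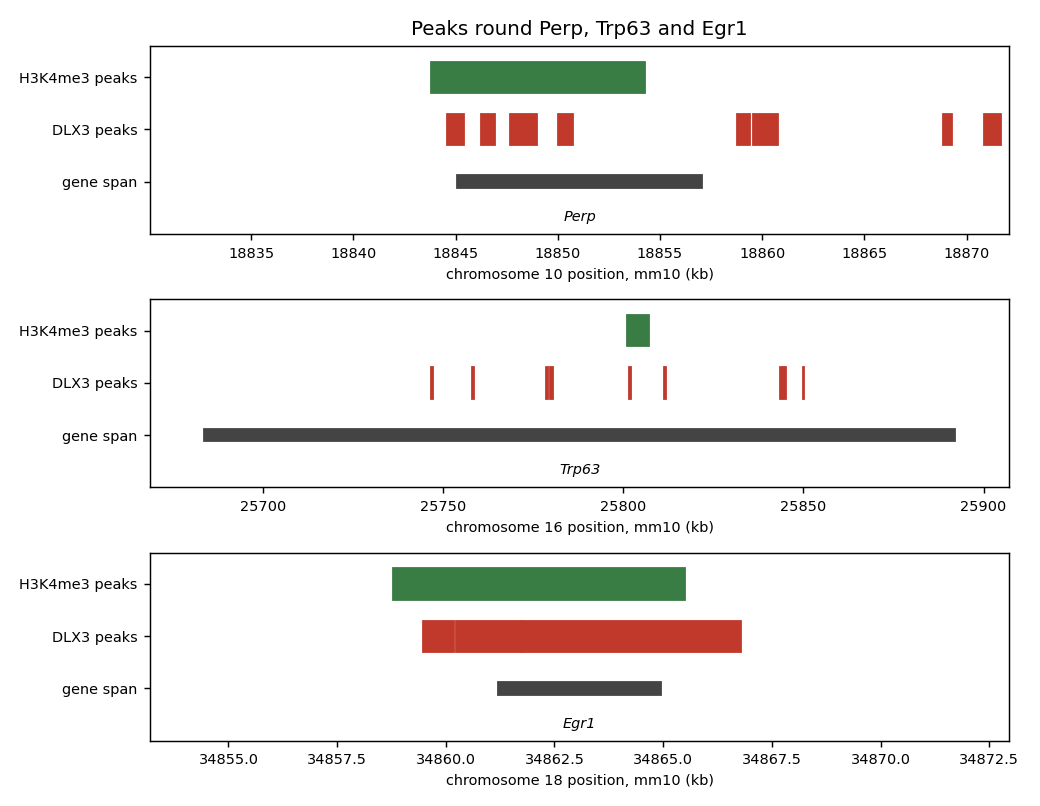
Maps of H3K4me3 peaks (green), DLX3 peaks (red) and the gene span (grey) at Perp, Trp63 and Egr1, drawn to scale against mm10 position in kb (horizontal axes). DLX3 peaks sit within and beside a 10484 bp H3K4me3 peak at Perp, spread over the span of Trp63 with 1 H3K4me3 peak of 6027 bp, and cover 99.7% of the short gene Egr1.

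Which gene groups lie near DLX3 was asked with 24 gene lists fixed before the data were examined. Genes of cell junctions, of keratinocyte transcription, of the cornified envelope and lipid barrier, and of hair keratins had DLX3 peaks within 5 kb of an end more often than random gene lists with the same number of H3K4me3-marked genes. The random lists were matched on the presence of H3K4me3 and not on its width or score. The share of H3K4me3 peaks with a DLX3 peak inside rose from 16.5% in the narrowest decile to 68.4% in the broadest. Wider or stronger H3K4me3 at the listed genes was therefore not accounted for. In the list of desmosome and tight junction genes, 28 of 31 (90.3%) had a peak, against 51.8% in matched random lists (central 95% of random lists, 11 to 21 genes; adjusted permutation p = 0.0016). Its highest-scoring members were Perp, Ctnnb1 (397.21; chromosome 9, 120932197 to 120933898), Cldn1 (385.71; chromosome 16, 26368044 to 26369859), the gene of the tight junction protein claudin 1, and Jup. Of the keratinocyte transcription factor genes, 41 of 50 (82.0%) had a peak, against 51.1% (19 to 32 genes; adjusted permutation p = 0.0016). Here the highest scores were at Fos (750.77; chromosome 12, 85472843 to 85477584), Jund (571.98; chromosome 8, 70698040 to 70699348) and Jun (460.99; chromosome 4, 95047944 to 95051325), which encode subunits of the AP-1 factor, and at Hes1 (519.87; chromosome 16, 30069323 to 30070955), a Notch target gene. DLX3 peaks covered 100% of the Fos span, 86.4% of Jund and 81.9% of Jun.

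Of the cornified envelope and lipid barrier genes, 34 of 46 (73.9%) had a DLX3 peak, against 47.7% (16 to 28 genes; adjusted permutation p = 0.0024). They included Padi3 and Padi1, peptidylarginine deiminase genes that share 1 peak (288.63; chromosome 4, 140813301 to 140814406), the lipase gene Lipm (242.73; chromosome 19, 34101705 to 34102323), and Ppl, the gene of periplakin (234.16; chromosome 16, 5134576 to 5135429). Of the hair keratin genes, 11 of 20 (55.0%) had a peak, against 24.5% (2 to 8 genes; adjusted permutation p = 0.0086), among them Krt72 (228.63; chromosome 15, 101770116 to 101771222), Krt73 (156.7; chromosome 15, 101797734 to 101799006), and Krt33a and Krt33b, which share 1 peak (153.85; chromosome 11, 100020934 to 100021589). The hair keratin genes lie in clusters, and their 11 genes rest on 12 distinct peaks. The Krt72 peak overlapped H3K4me3, though no H3K4me3 peak lay in that gene or within 1 kb of it. A peak within 5 kb of a listed gene can thus mark a neighbouring site, here and in the other lists. With a window of 1 kb the cornified envelope list no longer passed (22 of 46, 1.23-fold after 1.55-fold, adjusted permutation p = 0.515), and the hair keratin list turned from 2.25-fold to 0.593-fold of its random lists (2 of 20, adjusted permutation p = 0.769). Without matching on H3K4me3 the hair keratin list was at 1.54-fold and did not pass (adjusted permutation p = 0.165). The junction list did not pass with the top 20% of both peak lists by score, which also restricts the H3K4me3 marks used for matching (10 of 31, 2.20-fold after 1.74-fold with all peaks, adjusted permutation p = 0.0640), and the transcription factor list did not when peaks near immediate-early and heat-shock genes were left out (34 of 50, 1.34-fold after 1.61-fold, adjusted permutation p = 0.0590), an alternative chosen after the data were seen. In that setting its 7 immediate-early and heat-shock members stayed in the list and could have no peak, so the lower count was built in. With these 7 members left out instead, 34 of the remaining 43 had a peak (adjusted permutation p = 0.0024).

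**Figure D3:**
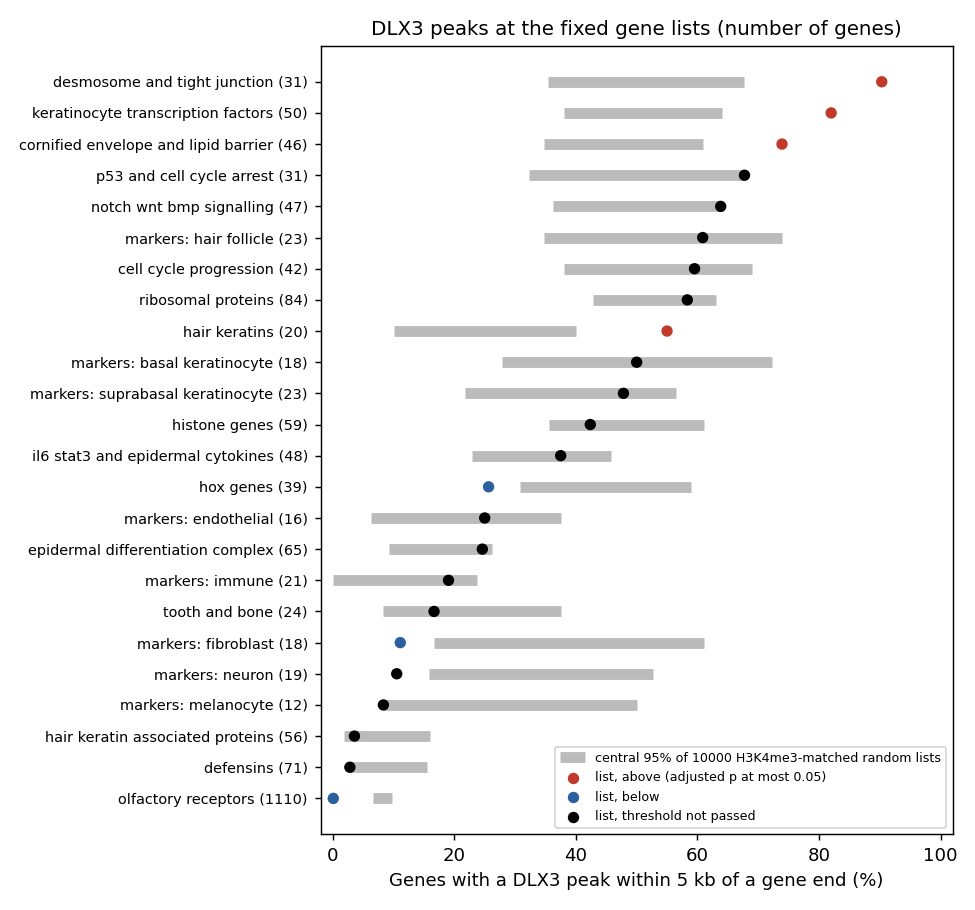
Percent of genes with a DLX3 peak within 5 kb of a gene end (horizontal axis) in each of the 24 gene lists (vertical axis, number of genes in brackets). Points are the lists, coloured by whether the adjusted p was at most 0.05, and grey bars are the central 95% of 10000 H3K4me3-matched random lists; 4 lists stand above and 3 below.

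Of the 24 lists, 3 lay below their random lists: olfactory receptors, Hox genes and fibroblast markers. Of 1110 olfactory receptor genes, 1 (0.0901%) had a DLX3 peak, against 8.15% (adjusted permutation p = 0.0016); it was Olfr455 (143.01). Of the Hox genes, developmental homeobox genes of body position, 10 of 39 (25.6%) had one, against 45.2% (adjusted permutation p = 0.0473), with Hoxc13, a hair regulator gene, highest at 249.08 (chromosome 15, 102920487 to 102921417), followed by Hoxc8 and Hoxc6 with a shared peak at 115.6 and Hoxa4 at 114.32. Of the fibroblast markers, 2 of 18 (11.1%) had one, Mfap5 (77.07) and Fbn1 (59.49), against 39.3% (adjusted permutation p = 0.0473). The Hox call held in 6 and the fibroblast call in 7 of 13 alternatives, and the olfactory receptor call in 13 of 13. The Hox list went from 0.567-fold of its random lists to 0.981-fold with a 20 kb window. Under rotation, which sets no H3K4me3 match, the Hox list stood at 2.46-fold (adjusted permutation p = 0.228) and the fibroblast list at 0.971-fold.

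The other 17 lists did not pass the threshold. In the epidermal differentiation complex, the chromosome 3 cluster of late differentiation genes, 16 of 65 genes (24.6%) had a DLX3 peak, against 17.5% (adjusted permutation p = 0.253), with Pglyrp3 (147.5), S100a11 (142.6), Lce6a (124.85) and S100a13 (121.36) highest. Among suprabasal keratinocyte markers 11 of 23 did, against 38.6% expected (0.614), led by Dsc1 (243.49), Krt80 (196.58), Sbsn (158.01) and Dmkn (101.78), and among basal keratinocyte markers 9 of 18 did, against 49.6% (1), led by Itgb1 (133.82), Krt5, Krt14 and Cd44 (84.12). Hair follicle markers had peaks at 14 of 23 genes (0.682), with Krt17 (470.51), Tcf3 (255.19), Hoxc13 and Msx2 (246.15) highest. Tcf3 here is the gene of that symbol on chromosome 10, and its standing as a hair follicle marker was not checked. Notch, Wnt and BMP signalling genes had 30 of 47 (0.201), with Hes1, Ctnnb1, Id3 (299.89) and Notch1. Genes of p53 and cell cycle arrest had 21 of 31 (0.162), with Perp, Btg2 (291.17), Sfn (238.25) and Plk3 (186.69). Genes of cell cycle progression had 25 of 42 (0.682), with Cdk4, Cdc6 (412.99), Birc5 (397.12) and Orc1 (388.72). Genes of IL-6, STAT3 and epidermal cytokines had 18 of 48 (0.683), with Stat3, Nfkbia (339.16), Jak2 (137.43) and Il22ra1 (125.23).

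Tooth and bone genes had DLX3 peaks at 4 of 24 (adjusted permutation p = 0.771), namely Runx2 (104.24), Fam20c (75.54), Alpl (63.01) and Fam20a (51.27). Ribosomal protein genes had 49 of 84 (0.589), against 53.2% in matched random lists. Histone genes had 25 of 59 (0.589) on 11 distinct peaks; the highest, 160.89, was at H13, which encodes a peptidase and shares only the symbol pattern, followed by H2ac8, H2bc8 and H2bc7 with a shared peak at 111.12. Hair keratin-associated protein genes had 2 of 56 (0.532), Krtap3-3 (65.67) and Krtap8-1 (53.29), and defensin genes 2 of 71 (0.253), Defb26 (58.12) and Defb1 (53.58). Among markers of other cell types, immune markers had 4 of 21 (0.640), against 12.6% in matched random lists. They were Cd3g (131.11), Coro1a (110.28), Cd52 (54.02) and Tyrobp (50.8). The peaks at Cd3g and Tyrobp overlapped H3K4me3, though neither gene had it within 1 kb of an end. Endothelial markers had 4 of 16 (0.816), against 19.8%, at Eng (102.19), Flt1 (75.33), Pecam1 (57.62) and Tie1 (50.8). Melanocyte markers had 1 of 12 (0.290), against 27.6%, at Dct (117.97). Neuron markers had 2 of 19 (0.0564), against 35.2%, at Rbfox3 (57.98) and Grin1 (56.05).

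The H3K4me3 list was used to ask which cell types and programmes had marked genes in the isolated cells. Lists of keratinocyte regulators, junctions, hair follicle, growth and protein synthesis stood above random protein-coding lists, in which 59.3% of genes were marked within 1 kb of an end, and immune and endothelial markers stood below. Marked genes made up 46 of 50 keratinocyte transcription factor genes, 29 of 31 junction genes, 43 of 47 Notch, Wnt and BMP genes, 41 of 42 cell cycle progression genes, 81 of 84 ribosomal protein genes and 51 of 59 histone genes (adjusted permutation p = 0.0004 for each). They made up 39 of 46 cornified envelope and lipid barrier genes, 28 of 31 genes of p53 and cell cycle arrest and 22 of 23 hair follicle markers (adjusted permutation p = 0.0010 for each), 31 of 39 Hox genes (0.0168) and 16 of 18 basal markers (0.0171). Below random lists were the epidermal differentiation complex with 13 of 65, immune markers with 2 of 21, olfactory receptors with 1 of 1110, keratin-associated proteins with 0 of 56 and defensins with 0 of 71 (adjusted permutation p = 0.0004 for each), tooth and bone genes with 7 of 24 (0.0070) and endothelial markers with 4 of 16 (0.0171).

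The H3K4me3 threshold was not passed by suprabasal markers with 15 of 23 (adjusted permutation p = 0.751), fibroblast markers with 12 of 18 (0.751), melanocyte markers with 5 of 12 (0.415), neuron markers with 11 of 19 (1), cytokine genes with 26 of 48 (0.651) and hair keratins with 7 of 20 (0.0584). With the peaks at or above the median score, the cornified envelope (1.02-fold), basal (1.37-fold, adjusted permutation p = 0.302), Hox (1.01-fold) and histone lists no longer passed above random lists. Fibroblast markers (2 of 18, 0.275-fold, adjusted permutation p = 0.0213) then stood below random lists. So did neuron markers (0 of 19) and hair keratins (0 of 20), with an adjusted permutation p of 0.0004 for each. Histone genes went from above random lists to 0.628-fold of them (adjusted permutation p = 0.0316). With the top 20% of peaks the immune (1 of 21, adjusted permutation p = 0.254) and endothelial markers (0 of 16, adjusted permutation p = 0.127) no longer passed.

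The 10 highest-scoring DLX3 peaks fell at 2 heat-shock genes, at 1 immediate-early gene and at 7 positions outside protein-coding genes. Hspa1a, a heat-shock protein gene, had a peak of score 2523.19 (chromosome 17, 34967220 to 34970200), Hsp90aa1, a chaperone gene, 1667.44 (chromosome 12, 110684739 to 110691150) and Egr1, an immediate-early transcription factor gene, 1441.38 (chromosome 18, 34861759 to 34866802). The peaks at Hspa1a and Egr1 overlapped H3K4me3, and the other 8 of the 10 did not. The highest score, 3100, was shared by a peak of 7948 bp on chromosome 7 (12010148 to 12018095), 27177 bp from the pheromone receptor gene Vmn1r77, and a peak on chromosome 17 (39842883 to 39848942) that overlaps the ribosomal RNA pseudogene Rn18s-rs5 and lies 104607 bp from Esp38. The remaining 5 lay between positions 3113143 and 3179476 on chromosomes 18, 4 and 6. Their scores were 2951.85 (chromosome 18, 3117814 to 3120849) and 1594.52 (3113143 to 3116329), both nearest to Vmn1r238 at 3160 and 7756 bp, 2509.82 (chromosome 4, 3175502 to 3179476) and 1415.16 (3164942 to 3165714), both nearest to Vmn1r2 at 4485 and 6755 bp, and 1472.43 (chromosome 6, 3132258 to 3135597), nearest to Samd9l at 238329 bp. A MACS score grows with read number and peak width, so it ranks enrichment of reads and not the share of cells or alleles bound. Whether the 7 peaks outside protein-coding genes reflect binding of DLX3 was not tested, and the IgG library was not analysed here. The lists were used as deposited, with no filter here for repeats or regions prone to artefacts.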

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

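The alternatives that left out immediate-early and heat-shock genes, the peaks near them or the 50 highest-scoring peaks, matched on gene density or length, used the gene span, any peak base or autosomes only were chosen after the data were seen. The overlap of DLX3 with H3K4me3 stayed past its threshold under all 7 alternatives run, between 25.3% (top 20% of both lists) and 44.2% (within 1 kb), as did the shares at gene ends, between 25.4% and 36.1% for DLX3 and between 41.1% and 73.9% for H3K4me3, and the odds ratio by score, between 1.86 and 3.47. DLX3 lists above random lists numbered 4 in the main setting, 2 with a 1 kb window, 8 without matching on H3K4me3 and 13 with rotation, which also sets no H3K4me3 match. Those below numbered 3 in the main setting, 1 with the top 20% of both peak lists, 1 with rotation, 1 without peaks near immediate-early and heat-shock genes, and 5 with the gene span and 5 kb. Directions of DLX3 folds reversed for hair keratins (0.593-fold), cytokine genes (0.906), basal markers (0.685), immune and endothelial markers (0 each) and keratin-associated proteins (1.21) with a 1 kb window, and for the last with 20 kb (1.49) and with matching on length (1.17). With stricter peaks, where the H3K4me3 marks used for matching changed too, they reversed at the median score for the epidermal differentiation complex (0.880), basal (0.804) and endothelial markers (0.878), ribosomal proteins (0.788) and histones (1.03), and in the top 20% for the complex (0.410), cytokine genes (0.494), ribosomal proteins (0.784) and basal, immune and endothelial markers (0 each). Without matching they reversed for the complex (0.687), immune (0.532) and endothelial markers (0.698) and histones (1.18), with rotation for Hox genes (2.46), histones (5.77) and tooth and bone genes (1.47), with the gene span for ribosomal proteins (0.979), and on autosomes for basal markers (0.987). Of these lists, hair keratins and Hox genes had passed the threshold in the main setting, and histones passed it under rotation. H3K4me3 lists above numbered 11 in the main setting, 7 with peaks at or above the median score and 7 with the top 20%; those below numbered 7 in the main setting and 11 at the median score. H3K4me3 directions reversed at the median score for fibroblast (0.275) and suprabasal markers (0.645) and histone genes (0.628), in the top 20% for cornified envelope genes (0.619), basal (0.632), suprabasal (0.495) and fibroblast markers (0), Hox (0.730) and histone genes (0.289), and with 2.5 kb for neuron markers (1.02). The cause was not tested. Over single lists, 245 DLX3 results kept direction and side of the threshold, 23 newly passed, 16 no longer passed and 28 reversed; for H3K4me3 these were 77, 4, 5 and 10. Motif searches and windows round transcription start sites were planned and not run, for lack of sequence and strand. No paired analysis was possible because each antibody has 1 library. Read depth is unknown, so weaker sites that the authors' threshold left out cannot be told from absent ones.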

Other observations

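All tests in this part, and the immediate-early and heat-shock gene lists, were chosen after the result was seen.

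The widest H3K4me3 peak was at Tfap2a, an AP-2 transcription factor gene (18614 bp; chromosome 13, 40721832 to 40740445), followed by Gata3 (17243 bp; chromosome 2, 9868584 to 9885826), Ptch1, the Hedgehog receptor gene (16710 bp; chromosome 13, 63557541 to 63574250), Irx2 (15255 bp; chromosome 13, 72621745 to 72636999) and Zbtb7b (13846 bp; chromosome 3, 89383414 to 89397259). DLX3 peaks numbered 5 in the Tfap2a peak, 2 at Gata3, 3 at Ptch1, 1 at Irx2 and 5 at Zbtb7b, and there was none in the 11440 bp peak at Shh, a Hedgehog ligand gene, or the 11167 bp peak at Bcl6. The 15 broadest also included peaks at Kdm6b with Dnah2 (13729 bp), Aopep (13649 bp), Irf2bp2, Fosl2, Tnrc18, Zfp503, and Rhof with Setd1b. The broadest 5% of H3K4me3 peaks, 837 peaks of at least 4484 bp, marked 15 of 23 hair follicle markers, 21 of 47 Notch, Wnt and BMP genes, 13 of 39 Hox genes, 9 of 31 junction genes, 9 of 31 genes of p53 and cell cycle arrest, 8 of 46 cornified envelope and lipid barrier genes and 9 of 59 histone genes, each above H3K4me3-matched random lists (adjusted p at most 0.0432). None of the 20 hair keratin, 21 immune, 16 endothelial, 12 melanocyte or 19 neuron genes was marked by such a peak, and their random lists gave 0 to 3 genes at most, so no deficit was detectable.

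A hypothesis was that broad H3K4me3 domains favour keratinocyte transcription factor genes. The broadest 5% of peaks marked 30 of the 50 genes in that list, against 6.29% in H3K4me3-matched random lists (0 to 7 genes), so the association may hold beyond H3K4me3 presence. It was not particular to that list, which stood at 9.54-fold. The other lists above their random lists ran from 2.58-fold (histone genes) to 9.97-fold (hair follicle markers). A further hypothesis, that DLX3 peaks are packed more densely in the broadest domains than in those of middle width, was argued against: the broadest decile held 0.197 DLX3 peak centres per kb (0.189 to 0.205), and the middle deciles 0.198 and 0.204. Deciles 2 and 3, among the narrow peaks, held fewer, 0.156 (0.142 to 0.172) and 0.160 (0.146 to 0.174), so density was not constant over all widths. Whether the broad domains reflect cell identity was not tested.

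Strong DLX3 peaks stood over immediate-early and heat-shock genes, which respond quickly to stress and tissue handling. Of 58 such genes, 53 had a DLX3 peak within 5 kb (34 of 38 immediate-early and 19 of 20 heat-shock genes, against 54.8% in H3K4me3-matched lists). Scores were 825.38 at Atf3, 1239.99 at Hspa1b and 503.91 at Hsp90ab1. Genes of at least 1500 bp were ranked by the share of their span covered by DLX3 peaks. Of the top 20, 15 were immediate-early or heat-shock genes, with Fos, Egr1 (99.7%) and Ddit4 (97.1%) in front. Whether DLX3 was held at promoters alone was not decided. Of 21 such genes with DLX3 at their single marked end, 42.9% (24.5 to 63.5) had a peak at the other end too. In length-matched genes the share was 1.79% (0 to 9.52). The match was on length and not on DLX3 score or peak width. A wide peak at the marked end of a short gene can reach the other end, so promoter binding was not excluded. Signal spread along the whole of very active genes, as known for highly transcribed loci in ChIP, may contribute. The median share of span covered was 18.5% over 47 of the 58 genes, with 6 others left out for fewer than 3 matches. In genes matched on length and top DLX3 score it was 5.43% (2.79 to 9.23). Induction of the immediate-early and heat-shock genes while the cells were isolated could not be decided. Their median H3K4me3 score, 2936.07, was above that of other marked genes (1277.5), but no sample without isolation was used here. Real binding of DLX3 also stays open, with the IgG library not analysed here.

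Few DLX3 peaks lay on chromosome X, 153 or 0.846% of the list, against 2.89% of H3K4me3 peaks. A lower number of marked genes was argued against as the cause, since among genes with H3K4me3 20.5% (80 of 390; 16.8 to 24.8) had a DLX3 peak on X, below every autosome (46.4% to 61.0%). Whether a lower template dose of X is the cause was not decided: the median H3K4me3 score at marked X genes was 0.408 of the autosomal one, and raising the DLX3 score threshold on autosomes by that scale predicted an X to autosome ratio of 0.364, within the interval of the observed 0.367 (0.301 to 0.444), but a plain halving of scores predicted 0.497, outside it. The prediction of 0.364 assumes that DLX3 and H3K4me3 scores scale alike, which was not tested. Weaker H3K4me3 on X promoters did not account for all of it, as autosomal genes weighted to the H3K4me3 scores of X had a DLX3 peak in 37.6%. The labels give no sex, but 4 H3K4me3 peaks on Y, nearest to Kdm5d, Eif2s3y, Uty and Ddx3y (scores 99.92 to 272.41), show Y chromatin in that library (DLX3 has 0 peaks on Y); the share of male cells was not measured, and a biological difference in DLX3 binding on X was not tested and stays open.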
